A study of Mus musculus with 435 samples.

How the data were processed

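Single Nr5a1-eGFP positive cells of XY mouse gonads were sorted by flow cytometry with Draq7 to leave out dead cells, captured on Fluidigm C1 chips, and turned into cDNA with the SMARTer kit and into libraries with Nextera XT, per the labels' protocols. Libraries were read as 100 bp pairs. The labels give 25 M reads for E10.5 and E13.5 and 10 M reads for the other stages, and a medium chip for the first E13.5 capture and small chips for the others. The submitters' processing notes name the builds GRCm38.p3 and mm10. The aligner, the counting tool, the annotation and the rule by which cells and genes were kept are not given in the sources used here.

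The values deposited by the authors are RPKM per cell, for 16459 genes including eGFP and 400 of the 435 labelled cells. The other 35 cells were not used here. The unit was read from the values: times the exonic length of a gene in GENCODE M21, they took the same smallest step for most low genes of a cell. The step gave an implied depth of 0.856 to 13 M reads per cell. In the median cell 68.7% of low values (up to 20 reads) were whole multiples of the step within 0.05, which is too few to recover counts, so the branch of the design for normalized values was used and the branch for counts was not. Symbols were matched to GENCODE M21 on GRCm38, which found 15900. Of all values 65.7% were 0, and cells had a median of 5628 genes above 0 (1698 to 9514). Gapdh was near 0 and predicted pseudogenes of it were high. Of 88 markers fixed before the data were examined 79 were in the values, and the missing ones include the globin genes, Ptprc and C1qc.

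Cells with fewer than 3000 detected genes were left out, which removed 3, all at E16.5. Cells of wells 49 and 56 of the second E12.5 capture had nearly the same values (correlation 0.998; the next closest pair of cells had 0.701) and were averaged and counted as 1 cell. For each capture the mean RPKM over cells was taken, and log2(mean + 1) was fitted with limma 3.58.1 (trend, robust empirical Bayes) on genes with a mean of at least 1 in at least 2 captures. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Early against late captures were fitted as 2 groups (7 residual degrees of freedom) and neighbouring stages as a factor of 5 levels (4 degrees). E10.5 has 1 capture, and its spread was taken from the other stages. Class comparisons were blocked by capture (3 residual degrees of freedom for Sertoli-like and 4 for Leydig-like cells, both against cluster 8), and the changes within a class had 2 degrees.

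Cells were clustered by Ward linkage on the scaled log2(RPKM + 1) values of the markers, at 8 clusters. A possible doublet was a cell with at least 3 markers of each of 2 classes, and 7 were found and kept. Marker genes used for clustering were left out of the class comparisons. A class needed 5 cells in a capture. The groups, tests, gene lists, markers and the rule for naming genes were fixed before the data were examined. The Leydig-like comparison at 1 cell, the difference between classes at 2 cells, the contrast of E16.5 with E12.5 over all cells, the fits within sequencing runs, median-ratio scaling, the mean of log2 values and thinning of cells were added after the data were seen, as were the other alternatives named so in the closing part.

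Genes were named if they passed the threshold, did not overlap between the captures of the groups (for classes, changed the same way in every capture), reached 5 RPKM in the higher group, were not predicted gene models, and were among the 8 largest changes each way (5 for neighbouring stages). Up to 4 called members of each gene list were added, or values of up to 2 members where none was called. Statements about genes outside this rule, such as Sry and Emx2, were chosen as fixed markers or after their values were seen. Gene lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 and again with the correlation estimated. Adjusted p-values of lists are over the lists of a comparison. Some results for single genes are not reported here.

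Shares of cells with a marker at 1 RPKM or more, and the median Pearson correlation between cells of a capture, were compared by exact two-sided permutation over the 84 splits of the captures, with Wilson 95% intervals and, at 0 cells, the limit that 3 cells set. Depth was lower in the 10 M read run. Recovery was tested on simulated captures with the genes' own levels and spreads, in which 4 sets of 50 genes were changed by a known log2 amount. For changes of 1, 2, 4 and 6, the early against late fit found 6, 33, 50 and 50 of them and called 11 unchanged genes, the fit of E12.5 against E11.5 found 2, 20, 50 and 49, and the fit within cluster 8 found 0, 0, 13 and 36. The fit of the difference between classes found 0, 0, 4 and 17. The simulated noise was normal and independent between genes, and the changed genes had a mean of at least 5 RPKM. Recovery in the real captures can be lower, so a fit with 0 calls does not exclude changes of these sizes. Alternatives were another pseudocount (0.1), no filter on low values, no cell filter, other clusterings, other minimum numbers of cells, leaving out cells of other types, labelled depth as a covariate, no capture block, and leaving out each capture. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.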

Results

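RNA was sequenced from single somatic cells of the fetal mouse testis at 5 stages, E10.5, E11.5, E12.5, E13.5 and E16.5. The cells carried Nr5a1-eGFP, a green reporter for Nr5a1, the transcription factor of gonadal somatic precursors and their steroid-producing descendants, and were sorted for green fluorescence before capture in the wells of microfluidic chips (Fluidigm C1). The stages run from the undivided genital ridge, through the formation of testis cords between E11.5 and E12.5, to the fetal testis with Sertoli cells inside cords and Leydig cells between them. The series text gives 435 cells, with 64, 98, 76, 120 and 77 cells from the earliest to the latest stage. Values for 400 of them were used here, and 396 were kept as separate cells, with 59, 93, 67, 112 and 65 per stage.

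The 9 captures, 1 at E10.5 and 2 at every later stage, were the replicates. P-values therefore measure the spread between captures, which in the early against late tests includes differences between the stages of a group. The labels do not say how many embryos went into each capture. The kept captures held 59 cells at E10.5, 52 and 41 at E11.5, 30 and 37 at E12.5, 56 and 56 at E13.5, and 31 and 34 at E16.5. The median depth implied by the values was 7.91 M reads per cell at E10.5 and 8.1 and 7.83 M reads in the E13.5 captures, which the labels give as sequenced to 25 M reads. In the other captures, sequenced to 10 M reads per the labels, it lay between 2.2 and 3.24 M reads. Median genes detected per cell ranged from 4899 in the second E16.5 capture to 6503 at E10.5. The deeper sequencing run held E10.5 and E13.5 only, so run and stage are confounded except between E10.5 and E13.5 and between E11.5, E12.5 and E16.5.

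The share of cells with each of 29 marker genes at 1 RPKM or more was compared between the 3 early captures (E10.5 and E11.5) and the 6 late captures (E12.5 to E16.5), to ask which markers separate the indifferent gonad from the differentiating testis. Amh, the hormone that removes the female ducts and a product of Sertoli cells, was found in 0 of 59, 0 of 52 and 0 of 41 early cells, which allows shares of up to 5.09%, 5.77% and 7.32%. In the late captures it was found in 33.1% ± 18.2 of cells (SD, n = 6). Dhh, the hedgehog ligand by which Sertoli cells signal to the interstitium, was found in 0.641% ± 1.11 of early and 30.3% ± 13.7 of late cells. Cyp17a1, a Leydig cell enzyme of androgen synthesis, was found in 0.813% ± 1.41 of early and 11.7% ± 5 of late cells. Ptgds, the prostaglandin D synthase of Sertoli cells, was found in 3.55% ± 3.11 and 39.2% ± 18.2.

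None of the 29 markers passed an exact two-sided permutation test over the 84 splits of the captures, for which the smallest possible p is 0.0119, after adjustment over the markers. The smallest exact p was 0.0238, for Dhh, Ptgds and Cyp17a1, with an adjusted p of 0.207. Amh and Gata4 had an exact p of 0.0357. Within the sequencing runs, the early minus late difference was -38 percentage points in the 10 M read run and -23.2 in the 25 M read run for Amh, and -31.6 and -25.9 for Dhh. Sox9, the Sertoli cell fate gene, was found in 65.1% of early and 66.7% of late cells, with differences of opposite sign in the runs, -14 and 23.3 points. Mki67 and Top2a, genes of dividing cells, also differed in sign between the runs.

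Sry, the Y-linked switch of testis determination, was found at E11.5 only, in 5 of 52 cells of the first capture (9.62%, Wilson 95% interval 4.18 to 20.6) and 5 of 41 of the second (12.2%, 5.32 to 25.5). It was found in 0 of 59 cells at E10.5 and in 0 of 30 and 0 of 37 cells at E12.5, which allows shares of up to 5.09%, 10% and 8.11%, so a share at E12.5 as low as the lower bounds at E11.5 is not excluded at this depth. Emx2, needed for growth of the gonadal epithelium, was found in 42.4% of cells at E10.5 and in 0% and 2.94% of cells in the E16.5 captures, with 30.4% and 42.9% at E13.5. Between all early and late captures it was at 52.9% ± 13.6 and 32.6% ± 26.6 (exact p 0.274, adjusted p 0.508). On average the Emx2 shares at E11.5 and at E12.5 lay above that at E10.5, so the share did not fall steadily from E10.5. Ddx3y, on the Y chromosome, was found in 76% ± 3.92 of early and 73.6% ± 8.22 of late cells. Foxl2, a granulosa cell factor, and Pou5f1, a germ cell factor, were listed at 0 in all cells. Intervals and limits cover counting error only, and a cell without a marker in these values is a cell without a detected transcript.

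**Figure D1:**
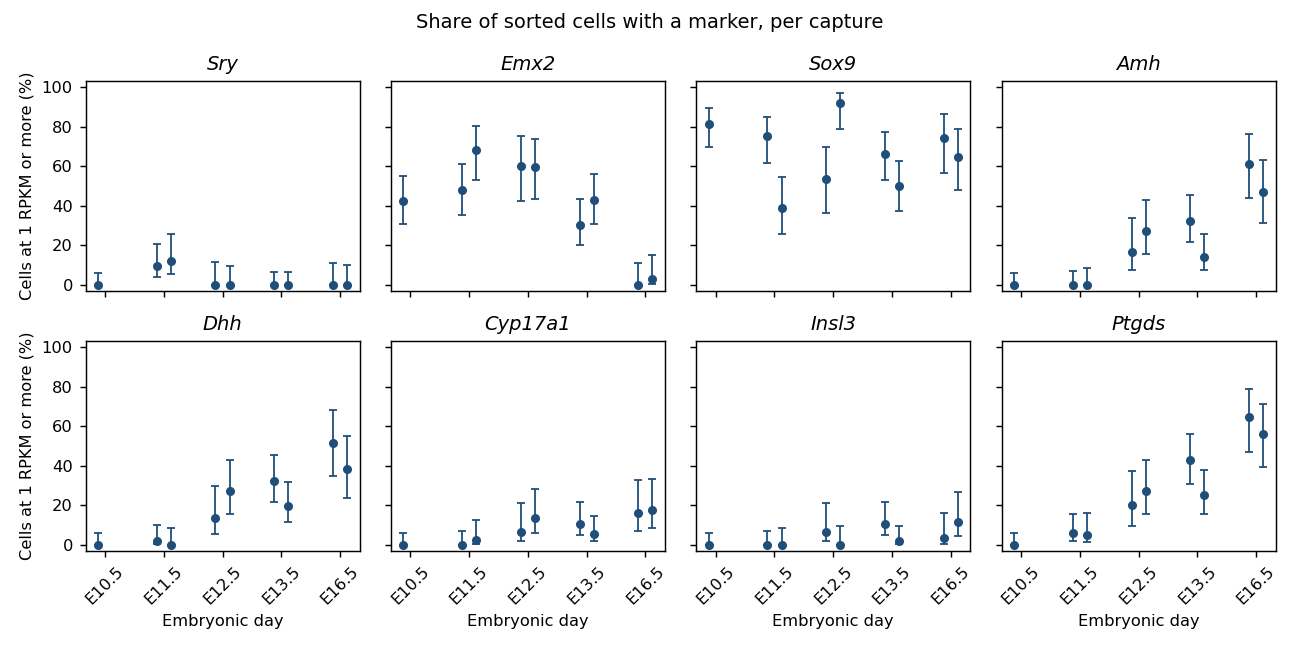
Share of cells (percent) with each of 8 markers at 1 RPKM or more against embryonic day, with 1 point per capture and Wilson 95% intervals as bars. Sry appears in the E11.5 captures only (9.62% and 12.2%), Amh from E12.5 on, and Emx2 is down to 0% and 2.94% at E16.5.

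Cells were grouped into 8 clusters on 79 cell type markers. Cluster 2, with 78 cells, was Sertoli-like and was led by Cst12, Serpina5, Etd, Ptgds and Rhox8. Cluster 1, with 8 cells, was Leydig-like and was led by Insl3, Cyp17a1 and Cyp11a1. Cluster 7, with 215 cells, was led by Upk3b, Shisa3 and Ecm1 and scored highest for the early progenitor markers without reaching a class name. Cluster 8, with 69 cells, was interstitial-like by its score, but its 10 leading genes held the smooth muscle markers Acta2 and Cnn1 and none of the interstitial markers. It is therefore called cluster 8 below. Clusters 4 and 5, with 3 and 7 cells, were endothelial-like and mesonephric-like, and clusters 6 and 3, with 15 cells and 1 cell, scored highest for the germ cell markers, with Dppa5a, Dppa3 and Dazl leading cluster 6 and Dppa4 cluster 3. Cluster 7 held 49 of 59 cells at E10.5, while the Sertoli-like cluster held 0 cells there, 5 and 7 cells in the E11.5 captures, and 17 of 31 and 13 of 34 cells in the E16.5 captures. Of cluster 6, 13 of 15 cells lay in the second E12.5 capture.

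**Figure D2:**
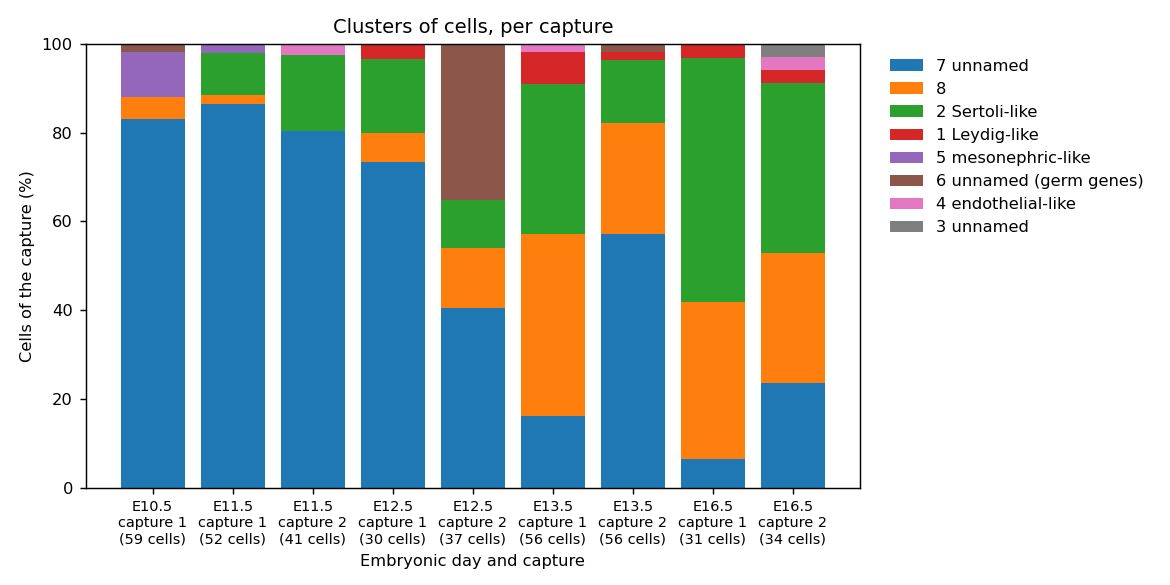
Percent of the cells of each capture (bars, with the number of cells under each) in each of the 8 clusters (colours), by embryonic day. Cluster 7 holds 49 of 59 cells at E10.5, and the Sertoli-like cluster 17 of 31 and 13 of 34 cells in the E16.5 captures.

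Late captures were compared with early ones over all sorted cells, to ask which genes differ between the stages before and after cords form. The shares of the clusters also differed between these captures, as given above. A change in a mean over all sorted cells can therefore be a change in the mix of cells. Defb19, a beta-defensin of Sertoli cells, rose by 7.26 ± 1.01 on the log2 scale (SE, n = 6 and 3 captures; limma adjusted p 0.0137), from 2.31 ± 1.66 to 820 ± 739 RPKM (SD). Amh rose by 3.92 ± 0.64 (adjusted p 0.0137), and Aldh1a1, a retinoic acid synthase, by 5.78 ± 0.795 (adjusted p 0.0137). Hsd3b1, a dehydrogenase of steroid synthesis, rose by 3.65 ± 0.495 (adjusted p 0.0062), and Inhba, the activin A subunit, by 4.4 ± 0.572 (adjusted p 0.00615). Gfra3, a receptor for the neurotrophic factor artemin, fell by 4.7 ± 0.595 (adjusted p 0.00615), from 47.4 ± 17.8 to 1.28 ± 2.03 RPKM. Rgs5, a regulator of G protein signalling, fell by 4.71 ± 0.777 (adjusted p 0.0137), Nr2f1, a nuclear receptor of mesenchyme, fell by 2.92 ± 0.607 (adjusted p 0.0481), and Lin28b, the repressor of let-7 microRNAs, fell by 2.41 ± 0.397 (adjusted p 0.0137). Fold changes were taken between log2 values of the mean RPKM + 1, which understates changes of genes near 0.

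Of 12313 genes tested, 57 rose and 14 fell in the late captures, and 1343 had an unadjusted p under 0.05. The count depended on single captures: it was 19 without the E10.5 capture, 40 without the first and 50 without the second E11.5 capture, 113 without the first E12.5 capture, 15 without the first and 37 without the second E13.5 capture, and 43 without the second E16.5 capture. Inhba, Hsd3b1 and Gfra3 passed in all 9 fits that left out 1 capture. The highest adjusted p in these fits was 0.0554 for Amh and 0.104 for Defb19, both without E10.5, and 0.0539 for Aldh1a1 without the first E11.5 capture. Rgs5, Lin28b and Nr2f1 reached 0.0929, 0.0803 and 0.254 without E10.5. Within the 10 M read run (6 captures), limma called 0 genes with 841 at an unadjusted p under 0.05, and in the 25 M read run (3 captures, with E10.5 alone on the early side) 421. Amh changed by 4.26 and 3.22 in the 10 M and 25 M read runs, Defb19 by 6.67 and 8.44, Hsd3b1 by 3.82 and 3.3, and Gfra3 by -4.65 and -4.81. Taking the mean of log2 values over cells in place of the log2 of the mean gave 48 genes higher and 49 lower, and without the filter on low values 0 were higher and 4 lower.

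**Figure D3:**
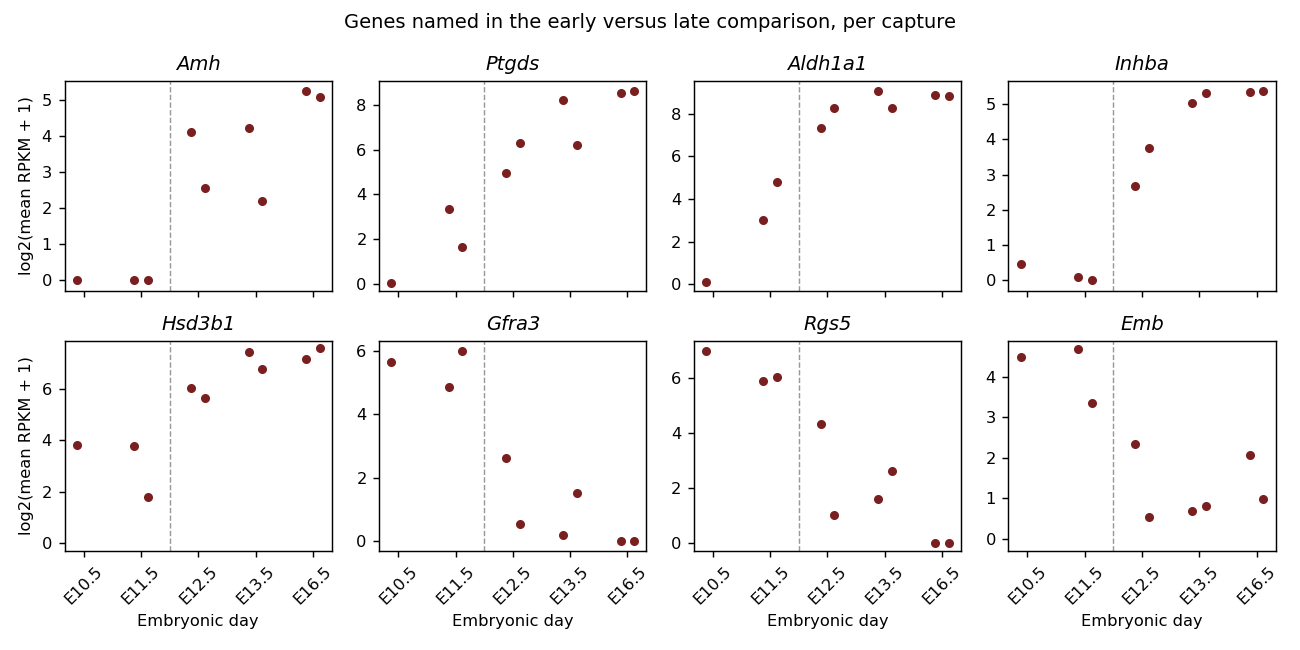
Log2(mean RPKM + 1) of 8 genes in each capture (points) by embryonic day, with a dashed line between the early and late captures. In every panel the 6 late points do not overlap the 3 early points, as the rule for naming genes requires.

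Among 20 genes of Sertoli differentiation, 6 rose, 0 fell and 14 had no call in the late captures, the risers including Defb19, Ptgds (5.45 ± 0.907, adjusted p 0.03) and Aard (3.61 ± 0.628, adjusted p 0.0188). Adjusted over the list alone, 14 rose and 0 fell, and the list's median change was 2.87 (camera adjusted p 5.82e-19; adjusted p = 0.256 with an estimated correlation). Of 16 steroidogenesis genes 1, Hsd3b1, rose (6 rose and 2 fell adjusted over the list alone; camera adjusted p 0.00338, 0.362 with an estimated correlation). Of 13 genes of the cord basement membrane, 3 rose, namely Col4a2 by 2.25, Col4a1 by 1.85 and Nid1 by 1.37 (camera adjusted p 0.00228, 0.349 with an estimated correlation). Adjusted over the list alone, 5 of these rose and 0 fell. Of the 9 fits that left out 1 capture, Nid1 passed in 4, Col4a2 in 2 and Col4a1 in 1, with adjusted p of up to 0.166 without E10.5, while Dcn and Aard passed in 7 and Ptgds in 5. Of 19 fibrillar collagen and interstitial matrix genes, Dcn alone rose, by 3.24 ± 0.505 (11 rose and 2 fell adjusted over the list alone), with a median of 1.16 (camera adjusted p 1.14e-06, 0.349 with an estimated correlation). Dcn was also the 1 gene to rise among 15 interstitial progenitor genes, while Nr2f1 fell (7 rose and 1 fell adjusted over the list alone; camera adjusted p 0.000662, 0.33 with an estimated correlation).

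Of 13 Lin28 let-7 and fetal growth genes, Lin28b fell and 12 had no call, 0 rose and 6 fell adjusted over the list alone, and all 13 had negative values, with a median of -1.39 (camera adjusted p 2.53e-08, 0.256 with an estimated correlation). HOX genes (median -1.16, camera adjusted p 0.000402, 0.301 with an estimated correlation), glycolysis (-0.39, 0.00531 and 0.301) and ovarian supporting cell genes (-0.88, 0.0248 and 0.43) had no called member, and adjusted over the list alone 1 glycolysis gene fell. G2 and mitosis genes had 0 calls of 30 (median 0.3, camera adjusted p 0.0441, 0.695 with an estimated correlation). Of 18 immediate early genes, Zfp36 rose by 2.47 and Egr1 by 2.05 (each passed in 3 of the 9 fits that left out 1 capture; 3 rose adjusted over the list alone), and the list had a camera adjusted p of 0.106. Adjusted over the list alone, 1 gene of the Wnt beta-catenin list rose and 3 fell, 3 hedgehog genes rose and 1 fell, and 2 angiogenesis genes and 1 cell cycle inhibitor fell. These 4 lists had 0 calls over all genes and camera adjusted p of 0.242, 0.172, 0.162 and 0.58.

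The remaining lists had 0 calls by limma in this comparison. Testis determination (camera adjusted p 0.116), cholesterol synthesis (0.837), Notch (0.516), epithelial junctions (0.43), DNA replication and S phase (0.362), oxidative phosphorylation (0.43), ribosomal proteins (0.525), endothelial markers (0.973), smooth muscle and peritubular markers (0.221) and coelomic epithelium markers (0.43) did not pass. The median and the test differed in sign for oxidative phosphorylation (median 0.02, mean -0.07) and endothelial markers (median 0.03). Germ cell, macrophage, erythroid, adrenal cortex, mesonephric and Y-linked lists had fewer than 5 tested members and no call, with medians of 0.24, 0.06, 1.04, 1.55, -0.69 and -0.09.

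Neighbouring stages were compared to place these changes in time. From E10.5 to E11.5, Kctd14, a tetramerisation domain gene of gonadal somatic cells, rose by 8.25 ± 0.671 (SE, n = 2 and 1 captures; adjusted p 0.00056), from 0.108 to 376 ± 241 RPKM. Gstm1, a glutathione transferase, rose by 4.84 ± 0.503 (adjusted p 0.00158), and Inha, the inhibin alpha subunit, by 3.29 ± 0.395 (adjusted p 0.00438). Hoxd10 rose by 4.35 ± 0.638 (adjusted p 0.0141), and Cyp11a1, the first enzyme of steroid synthesis, by 4.06 ± 0.748 (adjusted p 0.0454). Vtn, the matrix protein vitronectin, fell from 21.6 RPKM to being listed at 0 (adjusted p 0.0246). In all, limma called 47 genes higher and 1 lower, and the E10.5 capture was assumed to vary like the others, since it had no replicate. Without the second E11.5 capture 6 genes were called, and 27 without the first. In the fit with 6 calls, Kctd14, Gstm1, Inha and Tulp2 still passed, and Hoxd10, Cyp11a1 and Vtn reached adjusted p of 0.171, 0.355 and 0.197. These stages lie in different sequencing runs, and the mean of log2 values over cells gave 4 genes higher and 21 lower. Without the filter on low values 41 were higher and 164 lower.

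Dividing-cell lists were lower at E11.5 than at E10.5 without a called member: all 30 G2 and mitosis genes had negative values (median -0.97, camera adjusted p 7.34e-13, 0.317 with an estimated correlation), and 27 DNA replication genes had a median of -0.68 (1.11e-07 and 0.317). Testis determination genes had a median of 0.9, with 0 calls and 7 that rose adjusted over the list alone (camera adjusted p 5.2e-05, 0.285 with an estimated correlation). Of the Sertoli differentiation list Inha rose, and 6 rose adjusted over the list alone (camera adjusted p 0.000118, 0.4 with an estimated correlation). Fibrillar matrix genes had 0 calls and 3 that rose adjusted over the list alone (5.2e-05 and 0.317). Lin28 let-7 genes had 0 calls and 1 that fell adjusted over the list alone (0.000193 and 0.317).

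From E11.5 to E12.5, the step at which cords form and the stages share a sequencing run, limma called 0 of 12313 genes, with 961 at an unadjusted p under 0.05 and 1 call without the second E11.5 capture. The largest named values were 4.86 ± 0.823 for Defb19 (adjusted p 0.161), 4.36 for Cst9, a cystatin of Sertoli cells (0.413), and 3.06 for Hsd3b1 (0.201). Cdkn1c, a cell cycle inhibitor, had -1.83 ± 0.36 (adjusted p 0.231). Sertoli differentiation genes had a median of 1.22, and 7 rose adjusted over the list alone (camera adjusted p 5.81e-07, 0.544 with an estimated correlation). G2 and mitosis genes had a median of 0.88 (camera adjusted p 3.69e-07, 0.544 with an estimated correlation). From E12.5 to E13.5 limma again called 0 genes, with 563 at an unadjusted p under 0.05. Acta2, smooth muscle actin, had 4.41 ± 0.791 (adjusted p 0.362). The fibrillar matrix list had a median of 0.86 (camera adjusted p 6.68e-07, 0.346 with an estimated correlation), and 2 smooth muscle genes rose adjusted over the list alone (0.00102 and 0.362).

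From E13.5 to E16.5, across sequencing runs, Fshr, the receptor through which Sertoli cells answer follicle-stimulating hormone, rose by 4.61 ± 0.642 (SE, n = 2 and 2 captures; adjusted p 0.0192), from 0.544 to 38.3 ± 17.5 RPKM. Inha rose by 3 ± 0.322 (adjusted p 0.0111), and Gja1, the gap junction protein connexin 43, by 1.96 ± 0.299 (adjusted p 0.0361). Hmga2, a fetal chromatin protein and target of let-7, fell by 3.98 ± 0.533 (adjusted p 0.0167), and Cdkn1c fell by 2.66 ± 0.36 (adjusted p 0.0167). Npy, a neuropeptide, fell from 38.5 RPKM to being listed at 0 (adjusted p 0.0129). These are among 4 genes that rose and 7 that fell. The count was 0 without either E16.5 capture, 1 without the first E12.5 or the second E13.5 capture, 5 without the first E13.5 capture and 6 without the second E11.5 capture, and none of the 10 named genes passed in all 9 fits that left out 1 capture (Inha in 6, Npy and Hmga2 in 4, Fshr and Cdkn1c in 3, Gja1 in 1). The mean of log2 values over cells gave 46 higher and 17 lower, and the fit of these 2 stages alone and the fit without the filter on low values called 0. Among Sertoli differentiation genes 2 rose, and 5 adjusted over the list alone (median 1.43, camera adjusted p 4.86e-09, 0.459 with an estimated correlation). Of 6 coelomic epithelium markers, 4 fell adjusted over the list alone (median -1.94, camera adjusted p 0.000146, 0.459 with an estimated correlation).

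E16.5 was also compared with E12.5, a contrast added after the data were seen because both stages lie in the 10 M read run. Serpina5, the protein C inhibitor, rose by 6.2 ± 0.636 (SE, n = 2 and 2 captures; adjusted p 0.00228), and Inha by 3.56 ± 0.322 (adjusted p 0.00124). Of the steroid enzymes, Cyp17a1 rose by 5.54 ± 0.939 (adjusted p 0.031), from 9.88 ± 11.3 to 354 ± 113 RPKM, Cyp11a1 by 4.98 ± 0.611 (adjusted p 0.00644), and Hsd17b1 and Hsd17b3, which reduce androstenedione and estrone, by 5.74 and 4.8. Cyp17a1 and Cyp11a1 are among the leading genes of the Leydig-like cluster. That cluster held 1 cell in each E16.5 capture and 1 and 0 cells in the E12.5 captures. How far the means of these genes rest on such single cells was not tested. Myl7, a myosin light chain, fell by 6.52 ± 0.608 (adjusted p 0.00124), Hmga2 fell by 4.95 ± 0.533 (adjusted p 0.00284), and Fgf9, a signal that sustains Sertoli fate, fell by 4.14 ± 0.722 (adjusted p 0.0355). In all, 31 genes rose and 13 fell. The count was 4 and 8 without the first and the second E12.5 capture, and 10 and 5 without the first and the second E16.5 capture. Serpina5, Inha and Myl7 passed in all 9 fits that left out 1 capture, while Cyp17a1, Cyp11a1 and Fgf9 reached adjusted p of 0.149, 0.0684 and 0.223, and Hsd17b1, Hsd17b3 and Hmga2 passed in 6, 6 and 8. A pseudocount of 0.1 gave 17 higher and 17 lower, the mean of log2 values over cells 138 and 56, and the fit without the filter on low values 5 and 0.

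Of 20 Sertoli differentiation genes 5 rose from E12.5 to E16.5, and 15 adjusted over the list alone (median 2.32, camera adjusted p 3.05e-15, 0.199 with an estimated correlation). Of 16 steroidogenesis genes, Cyp17a1 and Cyp11a1 rose and Mc2r, the corticotropin receptor, fell by 3.95 (passing in 4 of the 9 fits that left out 1 capture; 8 rose and 1 fell adjusted over the list alone; camera adjusted p 1.18e-06, 0.203 with an estimated correlation). Each E16.5 capture held 1 Leydig-like cell, so the rises in this list may rest on few cells. Cholesterol synthesis genes had 0 calls and 6 that rose adjusted over the list alone (median 0.93, camera adjusted p 1.32e-08, 0.232 with an estimated correlation). All 6 coelomic epithelium markers fell adjusted over the list alone, with a median of -2.94 (camera adjusted p 2.08e-07, 0.199 with an estimated correlation), although Upk3b at -4.06 (adjusted p 0.0568) and Muc16 at -3.88 (0.0596) were not called over all genes. Immediate early genes had 0 calls and 6 that rose adjusted over the list alone (2.08e-07 and 0.363). Fibrillar matrix genes had 0 calls and 9 that rose adjusted over the list alone (1.23e-07 and 0.203). Acta2 rose by 4.59 ± 0.791 (adjusted p 0.0352) and passed in 5 of the 9 fits that left out 1 capture.

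Sertoli-like cells were compared with cells of cluster 8 of the same capture, to ask how the 2 clusters differ. This used the 4 captures of E13.5 and E16.5, which held at least 5 cells of each class, and left out the genes used for clustering. Rhox8, a homeobox gene of Sertoli cells, was higher in Sertoli-like cells by 6.57 ± 0.617 (SE, n = 4 captures; adjusted p 0.000602), at 188 ± 105 against 1.11 RPKM. Inha was higher by 5.87 ± 0.486 (adjusted p 0.000348), and Clu, the secreted chaperone clusterin, by 5.2 ± 0.41 (adjusted p 0.000297), at 2214 ± 600 against 93.8 ± 105 RPKM. Col1a1, fibrillar collagen, was at 2.28 RPKM in Sertoli-like and 138 ± 104 RPKM in cluster 8, a change of -5.28 ± 0.738 (adjusted p 0.00475). Pdgfrb, the receptor of perivascular mesenchyme, had -4.36 (0.00438), and Igf1, the growth factor, -3.7.

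Of 11301 genes, 307 were higher and 234 lower in Sertoli-like cells. The count was 190 without the first E16.5 capture, 228 without the second, and 220 without the second E13.5 capture, and 29 of the 48 named genes, Rhox8, Inha, Clu and Col1a1 among them, passed in all 4 such fits. Taking the mean of log2 values over cells gave 1097 higher and 426 lower, and without the filter on low values 1 gene was called. Of 11 Sertoli differentiation genes 7 were higher, Inha, Clu, Etd (6.09) and Hsd17b3 (4.76) among them (9 adjusted over the list alone; median 4.19, camera adjusted p 1.18e-11, 0.144 with an estimated correlation), as grouping by Sertoli cell markers leads one to expect. Of 10 epithelial junction genes 4 were higher, namely Krt18 (3.8), Pard6b (3.73), F11r (3.59) and Gja1 (2.85), and 5 adjusted over the list alone (0.000163 and 0.144). Of 6 interstitial progenitor genes 4 were lower, also adjusted over the list alone (median -3.96; 5.74e-06 and 0.144). Of 16 fibrillar matrix genes 8 were lower and 2 higher (10 and 2 adjusted over the list alone; 3.96e-06 and 0.243). Cluster 8 was grouped and scored on interstitial markers such as Dcn, Col3a1 and Col1a2. Lower values of the rest of these 2 lists in Sertoli-like cells, Col1a1, Pdgfrb and Igf1 among them, are thus also to be expected from the grouping. Of 12 cord basement membrane genes 4 were lower, Nid2 (-4.06) and Col4a2 (-2.08) among them, and Col18a1 was higher by 3.64 (5 lower and 1 higher adjusted over the list alone; 0.000471 and 0.144). Of the 4 fits that left out 1 capture, Col18a1 and Pard6b passed in 3, and Col4a2 and Krt18 in 1.

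Of 11 hedgehog pathway genes, Gas1 (-3.13) and Gli2 (-2.76), which receive and transmit the Dhh signal, were lower in Sertoli-like cells (3 adjusted over the list alone; median -1.82, camera adjusted p 0.000307, 0.181 with an estimated correlation). Gli2 passed in none of the 4 fits that left out 1 capture and Gas1 in 1. Of 17 glycolysis genes, Aldoa (1.78) and Pkm (1.37) were higher (4 adjusted over the list alone; 0.000307 and 0.181), and of 9 HOX genes, Hoxd10 (-4.39) and Hoxd8 (-3.73) were lower (3 adjusted over the list alone; 0.000307 and 0.144). Of 17 immediate early genes, Zfp36 (-2.93) and Egr1 (-0.74 ± 0.13, adjusted p 0.012) were lower (7 adjusted over the list alone; 0.000307 and 0.238). Egr1 reversed when captures with 2 cells of a class were let in, to 0.74. G2 and mitosis genes had 0 calls of 30 (median -0.56; 0.00104 and 0.327), and 2 growth genes, Mest (-3.35) and Peg3 (-2.45), were lower (3 lower and 1 higher adjusted over the list alone; 0.0127 and 0.181). Of 11 angiogenesis genes, Pdgfa (2.8) was higher and Cxcl12 (-4.02) and Nrp1 (-2.67) lower (1 higher and 3 lower adjusted over the list alone; 0.0272 and 0.247). Of the 4 fits that left out 1 capture, Nrp1 passed in none (adjusted p of up to 0.158), Pdgfa, Pkm and Hoxd10 in 1, Aldoa and Egr1 in 2, and Cxcl12 in 3. For 11 Wnt genes the median was -0.92 and the mean 0.06, Tcf7 was higher by 4.78, and the list did not pass (camera adjusted p 0.6).

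No capture held 5 Leydig-like cells. The planned Leydig-like comparison was therefore run, after the data were seen, on the 5 captures with at least 1 such cell. These held 8 Leydig-like cells in all, 4 in the first E13.5 capture and 1 in each of the others. Most Leydig-like values thus rest on 1 cell, and the SE and p hold the spread between cells as well as between captures. Adh1, alcohol dehydrogenase, was higher than in the cells of cluster 8 of the same capture by 8.77 ± 0.921 (SE, n = 5 captures; adjusted p 6.75e-08), at 1129 ± 959 against 1.3 RPKM. Inha was higher by 7.41 ± 0.821 (adjusted p 1.88e-07), and Nr5a1 itself by 3.69 ± 0.768 (adjusted p 0.00797), at 258 ± 112 against 18.3 ± 6.55 RPKM. Fdx1 (4.79) and Fdxr (4.19), which pass electrons to Cyp11a1, and Fdps (4.6 ± 0.582, adjusted p 3.19e-06), an enzyme of the cholesterol pathway, were also higher. Sostdc1, an antagonist of Wnt and BMP signals, had -6.17 ± 1.14 (adjusted p 0.00217), and Ptn, the growth factor pleiotrophin, -6.02 (0.00132).

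In the Leydig-like comparison 48 of 10629 genes were higher and 108 lower, with a median over all genes of -0.84. Means over 1 cell hold many zeros. Median-ratio scaling moved that median to -0.65 and gave 59 higher and 72 lower, and the mean of log2 values over cells gave 116 higher and 19 lower with a median of 0.21. Without the filter on low values 1 gene was called. The count was 481 without the E12.5 capture, 76 and 55 without the first and the second E13.5 capture, and 53 and 82 without the first and the second E16.5 capture, and Adh1, Inha, Nr5a1, Fdps and Sostdc1 passed in all 5 fits, while Fdxr, Dhcr7, Mcm5 and Defb19 passed in 4, and Fdx1 and Top2a in 2. Of 7 steroidogenesis genes 3 were higher, Fdx1, Fdxr and Nr5a1 (5 adjusted over the list alone; median 3.55, camera adjusted p 3.08e-13), and this list also passed with an estimated correlation (adjusted p = 0.0314). The cells had been grouped by steroidogenic markers, so a higher value of the rest of that list is expected from the grouping. Of 23 cholesterol synthesis genes, Dhcr7 (4.91) and Fdps were higher (4 adjusted over the list alone; 2.65e-13 and 0.17). Of 30 G2 and mitosis genes Top2a was lower by the test (-4.51), and 24 adjusted over the list alone (median -3.08; 2.88e-09 and 0.279). Of 27 replication genes 3 were lower, Mcm5 (-5.29) first (13 adjusted over the list alone; 5.16e-05 and 0.253). A gene found in only some cells can be missing from 1 Leydig-like cell yet present in a mean over many cells. Lower values of these 2 lists, and of genes such as Sostdc1 and Ptn, can therefore come in part from the cell numbers. How much of them is a difference between the classes was not tested. Of 9 Sertoli differentiation genes 2 were higher, Inha and Defb19 (4.2), with a median of -0.04 and a mean of 1.49 (2.37e-05 and 0.253).

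Within Sertoli-like cells, E16.5 was compared with E12.5 to separate changes inside the class from changes in its share. Serpina5 rose from being listed at 0 to 158 RPKM (adjusted p 0.0415), Enc1, an actin-binding protein, by 7.14 ± 0.622 (SE, n = 2 and 1 captures; adjusted p 0.008), and Hsd17b3 by 5.15 ± 0.629 (adjusted p 0.0286). Limma called 6 of 10166 genes, all of which rose, and the single E12.5 capture, with 5 cells, was assumed to vary like the others. The median change of all genes was 0.36, and 0.13 with median-ratio scaling. Serpina5 and Hsd17b3 lost their call when either E13.5 capture was left out, and Enc1 when the first was. Without the first E13.5 capture 0 genes were called and without the second 3, and 335 and 251 were called without the first and the second E16.5 capture. The mean of log2 values over cells gave 35 genes higher and 52 lower. Letting in the second E12.5 capture, with 4 cells, gave 0 calls, as did leaving out the filter on low values. Of 11 Sertoli differentiation genes Hsd17b3 rose (7 rose and 1 fell adjusted over the list alone; median 2.89, camera adjusted p 0.000499, 0.631 with an estimated correlation).

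Within cluster 8, Fos, an immediate early gene, rose by 4.15 ± 0.472 from E12.5 to E16.5 (SE, n = 2 and 1 captures; adjusted p 0.019), from 64.1 to 1153 ± 45.2 RPKM. Prss35, a serine protease-like protein, rose by 7.09 ± 0.768 (adjusted p 0.019) and Inhba by 6.41 ± 0.814 (adjusted p 0.0352). Limma called 6 genes higher and 1 lower of 10125, and the single E12.5 capture of 5 cells was assumed to vary like the others. The count was 0 without either E13.5 capture, and 594 and 364 without the first and the second E16.5 capture. It was also 0 with captures of at least 2 cells, without the filter on low values, and without the cell filter, which regroups the cells and gives the class 97 cells in place of 69. More genes were called lower than higher with the mean of log2 values over cells, at 74 higher and 176 lower. Clusters from variable genes put largely other cells under the class name of cluster 8, and that class gave 139 higher and 629 lower. Of 15 immediate early genes Fos rose (8 adjusted over the list alone; median 3.11, camera adjusted p 4.93e-11, 0.405 with an estimated correlation). G2 and mitosis genes had 0 calls and 10 that rose adjusted over the list alone (median 2.33; 1.49e-07 and 0.405), and DNA replication genes had a median of -1.2 (0.000966 and 0.426). The difference of the stage change between Sertoli-like cells and cluster 8, tested on captures with at least 2 cells of each, gave 0 of 11633 genes by limma, with 1049 at an unadjusted p under 0.05 and 119 calls without the second E12.5 capture.

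To ask whether cells become more or less alike, the median correlation between pairs of cells of a capture was taken over 4991 genes. It was 0.375 ± 0.0575 in the early captures (SD, n = 3) and 0.327 ± 0.0346 in the late captures (n = 6), and the difference of 0.048 had an exact two-sided permutation p of 0.143. The difference was 0.015 without E10.5 (p = 0.5), 0.0174 within named classes (p = 0.333), 0.0603 without the first E13.5 capture (p = 0.0179) and 0.1267 over genes with a mean of at least 100 (p = 0.0238). It was highest at E10.5, at 0.441, and lowest in the second E16.5 capture, at 0.283.

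In the annotation of the GRCm38 build (GENCODE M21), Defb19 (ENSMUSG00000050645.3) lies on chromosome 2 from 152576086 to 152580312 and Amh (ENSMUSG00000035262.5) on chromosome 10 from 80805243 to 80807648. Gfra3 (ENSMUSG00000024366.8) lies on chromosome 18 from 34689898 to 34720387 and Lin28b (ENSMUSG00000063804.8) on chromosome 10 from 45376620 to 45486395. Hsd3b1 (ENSMUSG00000027871.16) lies on chromosome 3 from 98852194 to 98859794, Kctd14 (ENSMUSG00000051727.14) on chromosome 7 from 97451323 to 97459557, and Inha (ENSMUSG00000032968.4) on chromosome 1 from 75507077 to 75510366. Fshr (ENSMUSG00000032937.5) lies on chromosome 17 from 88984952 to 89200675 and Serpina5 (ENSMUSG00000041550.4) on chromosome 12 from 104101113 to 104106137. Rhox8 (ENSMUSG00000064137.6) lies on the X chromosome from 37874778 to 37878944, Col1a1 (ENSMUSG00000001506.10) on chromosome 11 from 94936224 to 94953042, and Adh1 (ENSMUSG00000074207.10) on chromosome 3 from 138260991 to 138290698.

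**Figure D4:**
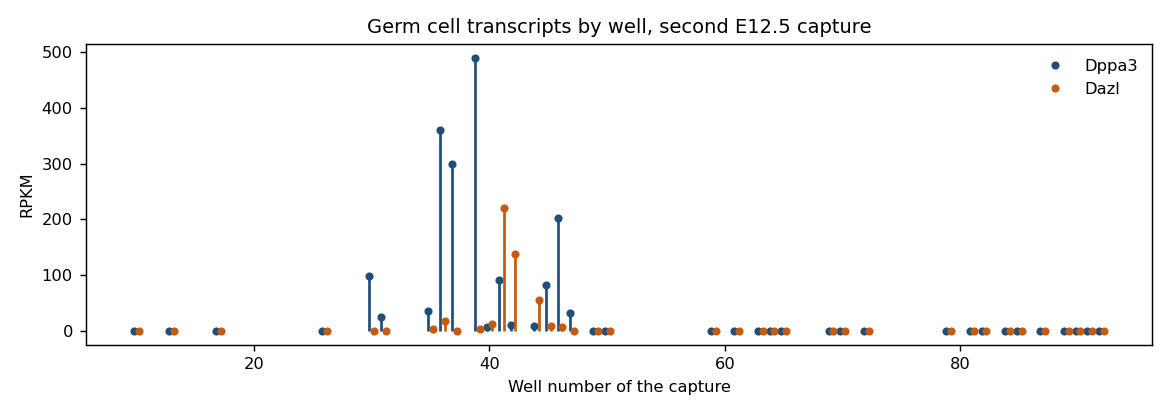
RPKM of Dppa3 and Dazl, 2 germ cell genes, in each cell of the second E12.5 capture (stems with points), against the well number of the capture. The cells with Dppa3 sit in wells 30 to 47, and the highest value is 489.6 RPKM.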

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

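The tests of the germ cell transcripts, and the minimum of 2 cells in the test of the difference between classes, were chosen after the data were seen. The tests of single captures covered the fixed markers and also genes named for early against late, Nr2f1 among them, which were picked from these data. Among 48 tests of 1 late capture against the other late captures, 4 found a capture far from the rest. The late captures pool E12.5, E13.5 and E16.5, so differences between stages can set a capture apart. Some tested markers, such as Foxl2 and Pou5f1, were at 0 in all late captures and could not be flagged. The count can therefore not be set against a chance rate of 1 in 20. Ddx4, a helicase of germ cells, was found in 10.81% of cells of the second E12.5 capture, and the next late capture had 3.571%. C1qa, a macrophage gene, was found in 2.941% of cells of the second E16.5 capture, which is 1 cell, and in none of the other late captures. Nr2f1 was at 0.004708 on the log2 scale in the second E16.5 capture, with the next late capture at 1.715. The reporter eGFP was at 11.47 in the first E16.5 capture, with the next at 10.67.

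Germ cell transcripts in the second E12.5 capture lay in neighbouring wells. Dppa3 (ENSMUSG00000046323.8, chromosome 6, 122626410 to 122630272), a gene of the germ line, was found in 13 of 37 cells, and these 13 were all the kept cells of wells 30 to 47 in a run of 13 neighbours (exact p 7.02e-09), with up to 489.6 RPKM. Germ cells among the sorted cells would be scattered over the well numbers, and the run of 13 argues against that. Neighbours are by well number here, as the place of the wells on the chip was not used. As Dppa3 defines the run, the other tests used other genes. Free germ cell RNA in the whole cell suspension would reach cells inside and outside the run alike, and 1 or more of 7 other fixed germ cell markers were found in 3 of 24 cells outside and 11 of 13 inside (Fisher exact p 2.64e-05), which argues against it as the whole source. Germ cell RNA that reached neighbouring wells may be the source, given these 11 of 13 cells: Dazl was in 9 and Ddx4 in 4 of them, each in 0 of 24 outside (which allows up to 3 of 24 cells), 2 of 10340 genes other than Dppa3 (Dazl and Sall4) passed a scan of all genes, and eGFP had a median of 878 RPKM in the run and 1040 outside. Germ cells in these wells would hold germ cell markers too, so the 11 of 13 cells do not tell germ cells and germ cell RNA apart. Other than germ cells among the sorted cells, no biological explanation was tested. Dppa3 was found in 0 of 30 cells of the first E12.5 capture and in 2 of 56 cells of the first E13.5 capture. Cluster 6, which was built with Dppa3 as a marker, is for the most part this run.

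Between Sertoli-like cells and cluster 8, 4 gene lists differed in their change from E12.5 to E16.5 by the test of the difference itself, on captures with at least 2 cells of each class, but none was kept with an estimated correlation (adjusted p 0.525, 0.525, 0.44 and 0.671 in the order below). DNA replication and S phase genes had the more positive change in Sertoli-like cells, with a median difference of 1.192 (1 gene adjusted over the list alone; camera adjusted p 0.000508). G2 and mitosis genes had the more negative change, with -1.808 (camera adjusted p 0.00237), and immediate early genes with -2.455 (2 genes adjusted over the list alone; camera adjusted p 0.000508). Ribosomal protein genes had 0.738 (camera adjusted p 0.00868). Immediate early genes answer to tissue dissociation as well as to signals, and no test here separates these.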

How the results depend on the processing

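The fits within the sequencing runs, of 2 stages alone, with median-ratio scaling, with the mean of log2 values over cells, with at least 2 or 3 cells, without possible doublets and without the germ-gene clusters, of thinned cells and of the similarity within cluster 7, and all alternatives of the E16.5 against E12.5 contrast over all cells, of the Leydig-like comparison and of the difference between classes, were chosen after the data were seen. The others were fixed before the data were examined.

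The early against late count of 71 was 61 with a pseudocount of 0.1 (52 of them shared), 63 without a cell filter (62 shared), 78 without cells of other types (67 shared), 48 with labelled depth as a covariate (43 shared), 63 with median-ratio scaling (63 shared) and 48 without the germ-gene clusters (45 shared). It was 97 with the mean of log2 values (31 shared). It was 0 in the 10 M read run, with 6 captures, and 421 in the 25 M read run, with 3 captures and 1 residual degree of freedom. Of the 84 splits of the captures into 3 and 6, 2 gave at least 71 genes. Most splits break up the captures of a stage, so this share cannot decide whether chance gave the count. The other of these 2 splits gave 107 and set the first E13.5 capture and both E16.5 captures apart. The split by sequencing run gave 0.

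Without a filter on low values the counts were 4 for early against late, 205 for E11.5 against E10.5, 5 for E12.5 against E11.5, 0 for E16.5 against E13.5, 5 for E16.5 against E12.5, 1 for Sertoli-like and 1 for Leydig-like cells against cluster 8, and 0 within Sertoli-like cells and 0 within cluster 8. Calls of named genes were kept 10 and lost 144 times in these fits. The prior degrees of freedom of the spread fell in these fits, from 7.8 to 1.37 in the first. For the changes below the cause was not tested. A pseudocount of 0.1 gave 98 genes for E11.5 against E10.5, 271 for Leydig-like cells, 179 within Sertoli-like cells and 37 within cluster 8. The mean of log2 values gave 25 for E11.5 against E10.5, 63 for E16.5 against E13.5, 194 for E16.5 against E12.5, 1523 for Sertoli-like cells, 87 within Sertoli-like cells, 250 within cluster 8 and 2 for the difference between classes. Fits of 2 stages alone gave 119 for E11.5 against E10.5 and 0 for E16.5 against E13.5.

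In other clusterings the class name of cluster 8 (69 cells) covers other cells, such as 284 with 6 clusters, so these counts also change the cells compared. Clusters from variable genes gave 258 for Sertoli-like cells against that class, 26 within Sertoli-like cells, 768 within that class and 1 for the difference between classes. With 6 clusters the count for Leydig-like cells against that class was 1994 and that within it was 1, and with 10 clusters the latter was 1. Without a cell filter, which regroups the cells too, they were 447 and 0. At least 10 cells gave 220 for Sertoli-like cells, with 3 captures left, at least 3 cells gave 0 within Sertoli-like cells, and at least 2 cells gave 0 within cluster 8. At that minimum Egr1 reversed in the Sertoli-like comparison, to 0.735 (adjusted p 0.798). Without the capture block the counts were 588 and 152. Swapping the classes within captures gave 1 of 8 swaps with as many as 541 genes (highest other 0) and 1 of 16 with as many as 156 (highest other 11), which are too few swaps for a share under 0.05.

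Leaving out 1 capture at a time gave 15 to 113 genes for early against late, 6 to 48 for E11.5 against E10.5, 0 to 1 for E12.5 against E11.5, 0 to 0 for E13.5 against E12.5, 0 to 11 for E16.5 against E13.5 and 4 to 48 for E16.5 against E12.5. It gave 190 to 377 for Sertoli-like and 53 to 481 for Leydig-like cells, 0 to 335 within Sertoli-like cells, 0 to 594 within cluster 8 and 0 to 119 for the difference between classes. Where this leaves a stage with 1 capture, it is assumed to vary like the others. Markers with a share past the threshold stayed at 0. With so few splits of the captures a marker can hardly pass after adjustment, so this count does not show stability. The difference in similarity of cells was 0.015 to 0.0677, and 0.1267 (exact p 0.0238) over genes with a mean of at least 100.

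Over all alternatives the named genes of early against late kept their call 265 times and lost it 184 times, those of the Sertoli-like comparison 637 and 178 times, and those of the Leydig-like comparison 372 and 90 times. For E16.5 against E12.5 it was 200 and 85, and within cluster 8 it was 44 and 54. The reversal of Egr1 was the 1 change of direction. Depth limits the genes detected: thinning cells to 1000000 implied reads took the median at E10.5 from 6503 to 5519, with the difference in similarity at 0.0475 and 0 markers past the threshold. As a marker can hardly pass with 84 splits, this count cannot show whether depth changes the shares.

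Alternatives meant for counts were not run, as the values are RPKM. At least 10 cells leaves no E12.5 capture for the changes within classes and no Leydig-like cells, and clusters from variable genes gave no Leydig-like fit. E11.5 cannot be compared with E10.5 without the E10.5 capture, nor stages within a class without its E12.5 capture.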

Other observations

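The tests in this part were all chosen after the results were seen. The first E13.5 capture lay nearer to E16.5 than the second on an axis of the 44 genes called between E12.5 and E16.5. The signed mean was 1.933 and 1.084 in the E13.5 captures, 0.264 and 0.253 in the E12.5 captures, and 4.456 and 4.203 in the E16.5 captures. Different shares of the cell clusters may account for part of the gap: weighting clusters 2, 7 and 8 alike left 34.05% of it (-29.44% to 69.54% over 1000 resamples of cells). These resamples hold no spread between captures, so the part due to shares cannot be told apart from other causes. The gap was -0.132 in the Sertoli-like cluster, 1.156 in cluster 7 and 0.289 in cluster 8. Chip size and capture date are open too, since 1 stage has captures on 2 chip sizes, and the embryos' exact age at E13.5 was not tested.

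The mean log2 value of 18 immediate early genes was 3.03 in the first and 1.379 in the second E11.5 capture, a difference between 2 single captures that was not tested. Over the 8 captures with both clusters, the score of Sertoli-like cells and that of cluster 7 had a Pearson correlation of 0.742 (permutation p 0.0421) and a Spearman correlation of 0.619 (permutation p 0.115). Without the 2 captures farthest from the median the Pearson correlation was 0.62 (permutation p 0.206) and the Spearman correlation 0.6, with 6 captures left. The first minus second capture gaps of Sertoli-like cells and cluster 7 were 2.264 and 1.536 at E11.5, and -0.498 and -0.099 at E12.5. They differed in sign at E13.5 (-0.008 and 0.823) and E16.5 (0.06 and -0.338). The correlations mix differences between stages with those between captures, and cluster 7 held 2 cells in the first E16.5 capture.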
